A study of Mus musculus with 3 samples.

How the data were processed

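Bulk RNA sequencing was done on proximal incisor mesenchyme of mice that carried a tamoxifen-inducible Cre recombinase under the Gli1 promoter and floxed alleles of Arid1a and Arid1b, called DKO in the labels. Per the labels' protocols, tamoxifen was injected at 1.5 mg per 10 g of body weight, the tissue was collected 4 days later, RNA was isolated with a Qiagen micro kit, and the mice were 1 month old. The labels gave 3 DKO libraries, numbered 1 to 3, and no other group. Nothing in the labels says whether the 3 libraries came from separate animals, so the SD and the tests measure only the spread between these libraries, which may be technical. Control mice were not analysed here, and no comparison between genotypes was made.

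The deposited values are normalized gene-level signal, and the name given to the deposited table calls them normalized counts. The 75th percentile over the listed genes was 44.7 in each of the 3 columns, so the deposited signal behaves as counts scaled to a common upper quartile, and totals per library of 986401, 958773 and 966163 were left unequal. Reads were aligned with TopHat2 2.0.8 to the mm10 build, per the submitters' processing notes. The read counter, the annotation, the handling of reads that match several places, the strand setting and any filter on low genes are not given in the sources used here. Values were not divided by gene length, so levels of different genes within a library also reflect transcript length. The columns were matched to libraries by the number in the column name and in the library name.

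Low values were examined for the worth of 1 read. In the 3 libraries 82.4%, 82.2% and 82.3% of the values up to 20 times the smallest value lay within 0.1 of a whole multiple of it, below the 95% needed to call whole reads recovered. Count models and the chi-square test of counting error planned for recovered reads were therefore not used, and the planned fallback, the number of genes with an SD of log2(value + 1) above 1, was reported. No value was 0. The smallest value was shared by 232, 233 and 199 genes, and whether it stands for 1 read or for a floor could not be settled. If it stands for 1 read, the totals correspond to 33863066, 34900647 and 41477624 reads, and counting error alone would be 5.40%, 5.24% and 4.83% at a value of 10 and 1.71%, 1.66% and 1.53% at a value of 100. These errors leave out library preparation and PCR.

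All logarithms were log2(value + 1), so a difference between low values is understated. Agreement between libraries, the spread of genes and the spread of lists used genes with a mean of at least 10. The 34 gene lists, which cover BAF family subunits, signalling pathways, tooth cell types, other cell types that the tissue could hold, and stress, interferon, mitochondrial and reference genes, held 367 genes, of which 343 were found by symbol and the rest were not analysed here. The level of a list was the percentile of its median among 10000 random lists of the same size drawn from genes with a mean of at least 10, while list members of any level entered, which places lists with weak members low. A list was called high or low where it lay outside the central 95% of random lists. That cutoff was not part of the prior design and was set after the percentiles had been seen, and a cutoff at percentiles 98 and 2 gave the same counts, 5 high and 13 low. The spread of a list was the range over the libraries of the median deviation of its members from their own means, set against 10000 random lists matched on mean expression in 20 bins (seed 1), for lists with at least 3 members. The share of random lists with a range as large was adjusted by the Benjamini-Hochberg method over 27 lists and called at 0.05, a threshold that the prior design did not state. This share is not a p-value, because the members of a list are regulated together and randomly drawn genes are not. On simulated shifts added to lists of 10 genes among 10388, the procedure called 0 of 20 lists with no shift, 4 of 20 at a log2 shift of 0.1, and 20 of 20 at 0.25, 0.5 and 1. Each gene's 3 deviations were first shuffled across libraries, which removes joint regulation. The 0 of 20 therefore does not give the rate of calls for lists regulated together, and smaller lists were not simulated. Differences between Arid genes within libraries were tested with an exact two-sided sign-flip permutation test.

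The gene lists, these measures, the alternatives and the rule for named genes were fixed before the data were examined. The rule took all subunits of the BAF family, the 4 members with the highest mean of every other list, list members with an SD of log2 above 1 at a mean of at least 10, the 10 genes with the highest mean, and the 10 with the largest log2 range at a mean of at least 100. Genes outside the rule are identified as chosen after their values were seen. Some genes of the fixed lists enter the list values but are not reported here by name. Gene positions are those of the deposited table in mm10, with the end moved down by 1, which made 18767 of the 18985 symbols shared with the GENCODE annotation identical in position. Exon lengths came from that annotation. Alternatives were another pseudocount, another filter on low values, rescaling to equal totals, division by exon length, leaving out each library and, added after seeing the data, removal of ribosomal RNA and mitochondrial genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.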

Results

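Gene expression was measured in 3 libraries of proximal incisor mesenchyme from DKO mice, the tissue that holds the Gli1-expressing stem cells from which the dentin and pulp of the continuously growing mouse incisor are renewed. Arid1a and Arid1b, the floxed genes, encode alternative DNA-binding subunits of the canonical BAF chromatin remodeling complex, and the series asks how this complex shapes the stem cell niche. Values are upper-quartile-scaled gene counts as deposited, given in normalized units as mean ± SD over n = 3 libraries or per library in the order of replicates 1, 2 and 3. The table listed 19381 genes, 15252 of them protein coding, and 10388 had a mean of at least 10. A value of at least 1 was reached by 14843, 14796 and 14674 genes in the 3 libraries and a value of at least 10 by 10399, 10349 and 10312.

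Transcripts of both floxed genes were measured in every DKO library. Arid1a (chromosome 4, 133679008 to 133756769, mm10) stood at 135.9, 129.8 and 132.6 (132.8 ± 3.04, SD, n = 3) and Arid1b (chromosome 17, 4994332 to 5347656) at 50.5, 50.7 and 50.8 (50.7 ± 0.156, SD, n = 3). The coefficient of variation of Arid1b, 0.309%, lay below the counting error even at a value of 100. That error was 1.71%, 1.66% and 1.53% in the 3 libraries if the smallest value is 1 read. The SD of Arid1b is therefore not a measure of its precision. Arid2 (chromosome 15, 96287518 to 96404992), the related subunit of the PBAF complex and not a target of the recombination, stood at 163.8 ± 3.36. Within libraries, Arid1a lay below Arid2 by a log2 difference of -0.30 ± 0.05, Arid1b differed from Arid2 by -1.67 ± 0.03, and Arid1a exceeded Arid1b by 1.37 ± 0.03, each in the same direction in 3 of 3 libraries. The exact two-sided sign-flip permutation test gave p = 0.25 for each, the smallest value that n = 3 allows. Division by exon length (11476, 12600 and 10737 bases for Arid1a, Arid1b and Arid2) gave -0.37, -1.69 and 1.32. Gene-level values include reads from exons outside the floxed part and from cells without recombination, so they do not check the deletion.

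The other subunits of the BAF family were expressed at closely similar levels in the 3 libraries. All 13 measured core subunits had a mean of at least 10, with means from 19.7 for Bcl7b to 210.5 for Smarca2. The ATPases that drive remodeling, Smarca4 and Smarca2, stood at 175.6 ± 12.2 and 210.5 ± 12.1, and the scaffold subunits Smarcc1 and Smarcc2 at 210.0 ± 10.6 and 194.2 ± 2.75. Smarcb1 (55.2 ± 1.38), Smarcd1 (49.0 ± 3.55), Smarcd2 (46.4 ± 1.09), Smarcd3 (35.5 ± 2.34), Smarce1 (134.9 ± 6.73) and Actl6a (46.5 ± 0.838) lay between. Among the remaining canonical subunits, Ss18 (108.3 ± 4.37) and Dpf2 (83.0 ± 3.48) were abundant, Ss18l1 was at 11.3 ± 0.705, and Dpf1 (4.69 ± 0.813) and Dpf3 (1.06 ± 0.237) were low. Of the PBAF subunits, Pbrm1 was at 252.9 ± 17.1, Phf10 at 76.9 ± 4.01 and Brd7 at 75.2 ± 4.39. The non-canonical subunits Bicral, Brd9 and Bicra were at 66.4 ± 1.22, 41.6 ± 4.06 and 23.7 ± 1.79. The coefficient of variation was at most 9.78% among members of these lists with a mean of at least 10, and the adjusted share of random lists with as wide a spread was 0.760 for the canonical, 0.878 for the core, 0.403 for the PBAF and 0.878 for the non-canonical subunits.

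**Figure D1:**
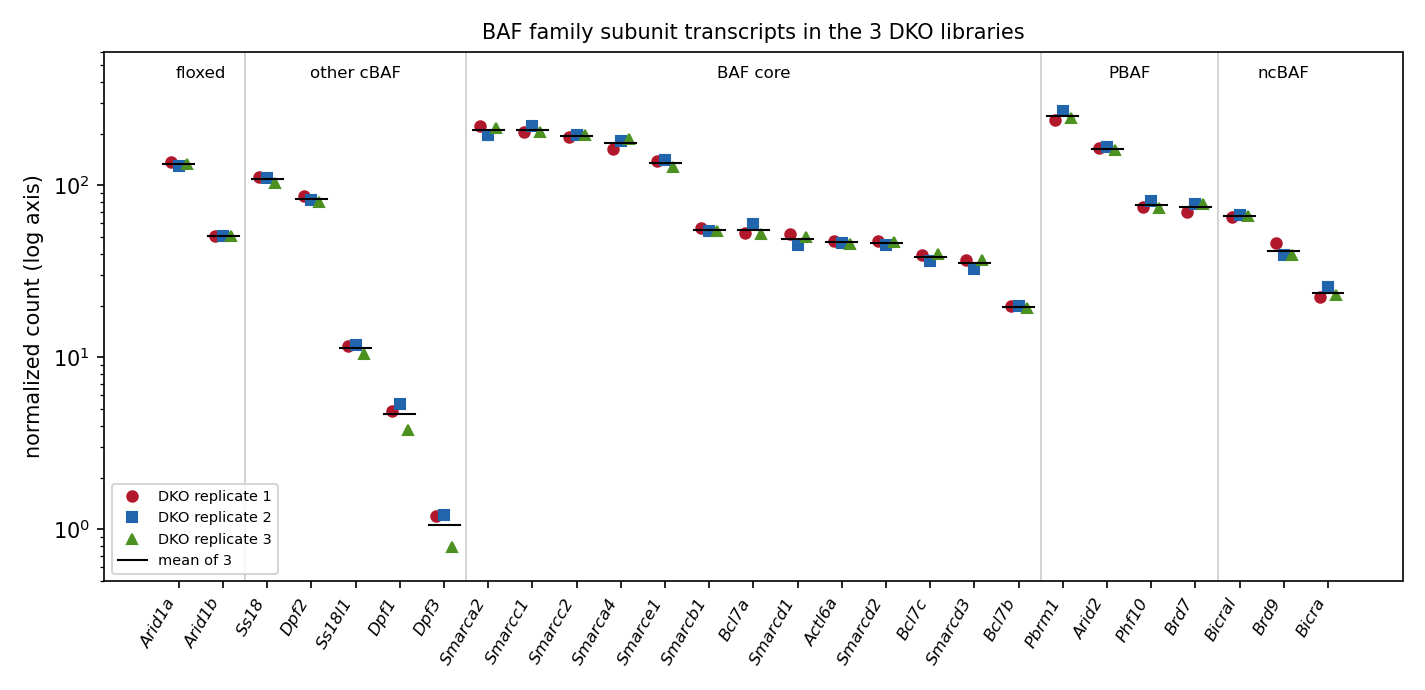
Normalized values of the BAF family subunits in the 3 DKO libraries, on a log axis, with a point for each library and a line at the mean of the 3. Arid1a lies at 132.8 ± 3.04, Arid1b at 50.7 ± 0.156 and Arid2 at 163.8 ± 3.36.

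Genes of the stem cell niche and of odontoblasts, the cells that secrete dentin, were among the most abundant. The niche list lay at percentile 100 of random lists, with Igfbp5 at 2749 ± 860, Prrx1 at 619 ± 57.9, Pdgfra at 610 ± 36.3 and Igf2 at 397 ± 46.7. The odontoblast list was also at percentile 100, with Col1a1 at 9461 ± 4518, Col1a2 at 4023 ± 1286, Dspp, the main non-collagen dentin protein, at 3174 ± 1963 and Sparc at 2319 ± 481. The BMP list lay at percentile 99.8, led by Bmpr2 (487 ± 8.74), Bambi (409 ± 32.7), Bmp2 (360.1 ± 29.4) and Id3 (317 ± 21.7). Mitochondrial genes, with mt-Co1 at 11336 ± 1428, and reference genes, with Actb at 1533 ± 179, completed the 5 lists called high. Eef1a1, a translation elongation factor, stood at 6723 ± 159. After division by exon length the niche list lay at percentile 72.9 and the BMP list at 97.0, and neither was then called high, while the odontoblast list stayed at 99.2. The random lists then came from genes with a mean of at least 10 per kilobase of exon. These changes therefore reflect that filter as well as length.

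Transcription factors of jaw and tooth mesenchyme were at percentile 96.2, with Dlx3 at 349 ± 30.7, Msx1 at 240.1 ± 29.2, Msx2 at 194.6 ± 8.56 and Dlx5 at 149 ± 5.35. Pulp genes lay at 94.7, with the matrix proteins Tnc at 1700 ± 83.1 and Vcan at 1674 ± 140.1. Macrophage markers were at 97.2, led by Mrc1 (267 ± 43.3) and Lyz2 (266 ± 54.6). The hedgehog list was at 65.7, the Wnt list at 69.2 and the cell cycle list at 60.5, and dental epithelium genes, with Enam at 209 ± 59.6 and Krt5 at 199 ± 48.3, lay at 49.2. Endothelial, mural and p53 target genes were at 17.0, 32.1 and 33.1. After division by exon length the tooth transcription factors lay at percentile 89.6, pulp genes at 13.5, dental epithelium genes at 0.70 and the core BAF list, at 79.3 as deposited, at 0.47, and the hedgehog, Wnt, cell cycle, endothelial, mural and p53 lists lay at 0. The filter of at least 10 per kilobase places lists of long or weakly expressed genes low. These values are therefore not an effect of length alone.

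Markers of blood, marrow and muscle were scarce. None of 8 neutrophil and 10 skeletal muscle genes reached a mean of 10, and their highest members were S100a9 at 1.36 ± 1.40 and Acta1 at 1.44 ± 1.30. The erythroid genes Hba-a2 and Hbb-bs were at 11.3 ± 3.15 and 10.7 ± 2.34, values that are uncertain because near-identical globin copies share reads. The only lymphocyte gene above 10 was Cd4 (14.0 ± 4.82), and the only adipose gene was Lipe (11.8 ± 1.16). Glia, osteoclast, cartilage, bone cell, dental follicle, FGF and immediate early genes and the canonical BAF subunits other than the floxed genes were the other lists called low, at percentiles of at most 1.26. The random lists were drawn from genes with a mean of at least 10 while list members of any level entered, so lists with weak members tend to be called low, and against genes of any level only the neutrophil, lymphocyte and skeletal muscle lists stayed low, 3 of 13. The X-inactivation transcript Xist stood at 3429 ± 323 in the 3 libraries. The Y-linked genes fixed beside it, Ddx3y, Eif2s3y, Kdm5d and Uty, were not among the listed genes.

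The libraries were alike for most genes. Pearson correlations of log2 values across 10388 genes were 0.980 between replicates 1 and 2, 0.977 between 1 and 3 and 0.986 between 2 and 3, and Spearman correlations were 0.978, 0.976 and 0.985. These are correlations across genes, which are not independent replicates. The median gene had an SD of log2 of 0.10. An SD above 1 was found for 49 genes, of which 38 were highest in replicate 1, 1 in replicate 2 and 10 in replicate 3. Without replicate 1 the count was 20.

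Interferon-stimulated genes set replicate 1 apart. All 9 members at a mean of at least 10 were highest there, and the list ranged over 2.37 on the log2 scale, a 5.17-fold difference between the highest and the lowest library (adjusted share 0.00045, the smallest the procedure gave). Oasl2, an antiviral effector, was at 357, 64.4 and 68.8. Ifit3, Isg15 and Ifit1 exceeded the mean of the other libraries 6.56-, 5.94- and 5.97-fold in replicate 1, and Irf7, Rsad2, Usp18 and Bst2 were also highest there. Rnf213 showed the same order, at 568, 180 and 196. Without replicate 1 the range was 0.12 (adjusted share 0.386). Replicate 1 also had the highest share of the ribosomal RNA gene CT010467.1 (7.27%, against 4.98% and 4.66%) and of mitochondrial genes (5.11%, against 4.14% and 4.16%).

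Several genes of mineralized matrix were lowest in replicate 2, while others from the same lists were not. Dspp was at 4959, 1072 and 3489, a value 3.94-fold lower in replicate 2 than the mean of the others. Phex, a peptidase of mineralizing cells, was at 377, 79.7 and 339, Col11a2 at 422, 141 and 412 and Col1a1 at 9950, 4719 and 13715. The osteocalcin genes Bglap and Bglap2 were at 363, 104 and 394 and at 118, 43.1 and 153, and may share reads as close copies. Mmp20, a protease of enamel matrix, was at 79.6, 19.1 and 91.4. The odontoblast list ranged over 0.55 (adjusted share 0.00045), with 7 of 12 members lowest in replicate 2, and the call ended without that library (range 0.03, adjusted share 0.871). Bone cell genes ranged over 0.30 (adjusted share 0.0254), and their call ended without replicate 1 and with a pseudocount of 10. Other members of these lists went differently. Col1a2 (2809, 3890 and 5371), Bambi (372, 419 and 436) and Ibsp (15.6, 27.3 and 30.9) were lowest in replicate 1, Sp7 (187, 182 and 176) was lowest in replicate 3, and Spp1 (48.8, 87.5 and 59.7) and the enamel matrix genes Amelx (54.6, 145 and 66.0) and Ambn (107, 181 and 148) were highest in replicate 2. Ibsp, Sp7, Amelx and Ambn were chosen after their values were seen.

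**Figure D2:**
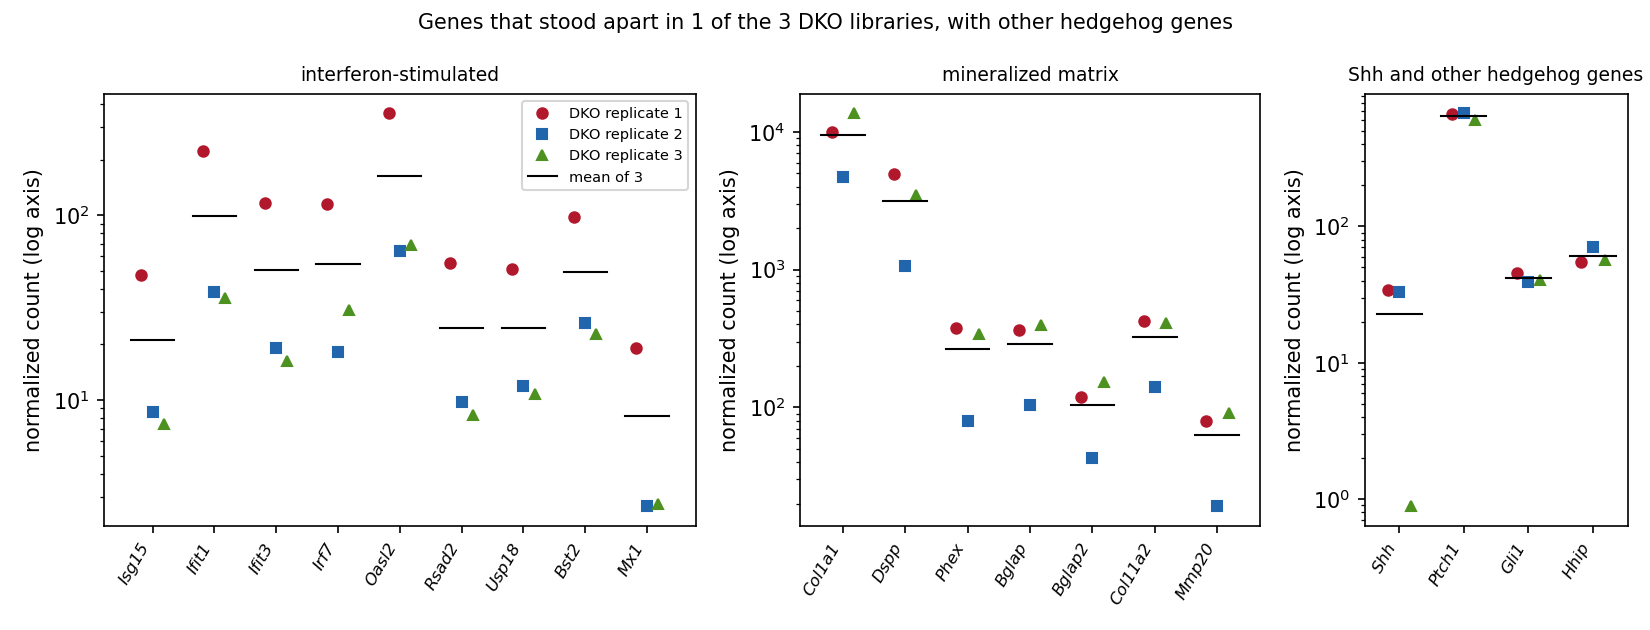
Normalized values in the 3 DKO libraries, on a log axis, of interferon-stimulated genes, mineralized matrix genes chosen for low values in replicate 2, Shh and 3 other hedgehog pathway genes, with a point for each library and a line at the mean. Interferon genes such as Oasl2 (357, 64.4 and 68.8) are highest in replicate 1, and Dspp (4959, 1072 and 3489) is lowest in replicate 2.

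Epithelial, vascular and macrophage markers also differed together between libraries. Dental epithelium genes ranged over 0.57 (adjusted share 0.00045), with 10 of 12 members highest in replicate 2, among them Krt5 at 180, 253 and 162, Krt14 at 123, 191 and 154 and Cdh1 at 126, 181 and 150. Without replicate 2 the range was 0.02. Endothelial genes ranged over 0.36 (adjusted share 0.00045), and all 10 were highest in replicate 3, with Vwf at 60.5, 67.9 and 107 and Cdh5 at 76.0, 81.2 and 107. Without replicate 3 the range was 0.03. Macrophage genes ranged over 0.40 (adjusted share 0.00045), and 10 of 12, Mrc1, Lyz2 and Csf1r among them, were lowest in replicate 1, whose omission ended the call.

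Cell cycle genes ranged over 0.26 (adjusted share 0.00045), with 13 of 16 lowest in replicate 1. Mki67, a mark of cycling cells, was at 236, 302 and 282, and Top2a at 217, 279 and 256. The call ended without replicate 1 and when genes were limited to means of at least 100. All 9 mitochondrial genes were highest in replicate 1 (range 0.38, adjusted share 0.00077), and without that library the range was 0.02 (adjusted share 0.827). Nuclear copies near-identical to mitochondrial genes may share their reads. The pseudogene Gm10925 was at 3740, 2913 and 3039, almost the values of mt-Atp6 (3748, 2915 and 3048). Gm28437 was at 3166, 2722 and 2518, beside mt-Co3 at 3166, 2723 and 2519, so the same reads appear to enter both. These genes were chosen after their values were seen. Wnt genes ranged over 0.18 (adjusted share 0.0125), with 12 of 17 highest in replicate 3. Wnt5a was at 293, 465 and 463. Immediate early genes ranged over 0.39 (adjusted share 0.0153), with 5 of 5 highest in replicate 3. The Wnt and immediate early calls ended without replicate 1 and without replicate 3.

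Niche genes ranged over 0.14 (adjusted share 0.0282) and mural genes over 0.19 (adjusted share 0.0466), and both calls were lost under several alternatives. Igfbp5 was at 1756, 3242 and 3248, Pdgfra at 568, 624 and 637 and Prrx1 at 559, 675 and 623. All of these were lowest in replicate 1, as were 9 of 18 niche genes. Coefficients of variation were 31.3% for Igfbp5, 5.95% for Pdgfra and 9.35% for Prrx1. In total 12 of 27 lists were called. The 15 others, with adjusted shares from 0.0743 for pulp genes to 0.971 for FGF genes, were the pulp, glia, osteoclast, p53, cartilage, dental follicle, hedgehog, BMP, FGF, reference and tooth transcription factor lists and the 4 BAF family lists.

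**Figure D3:**
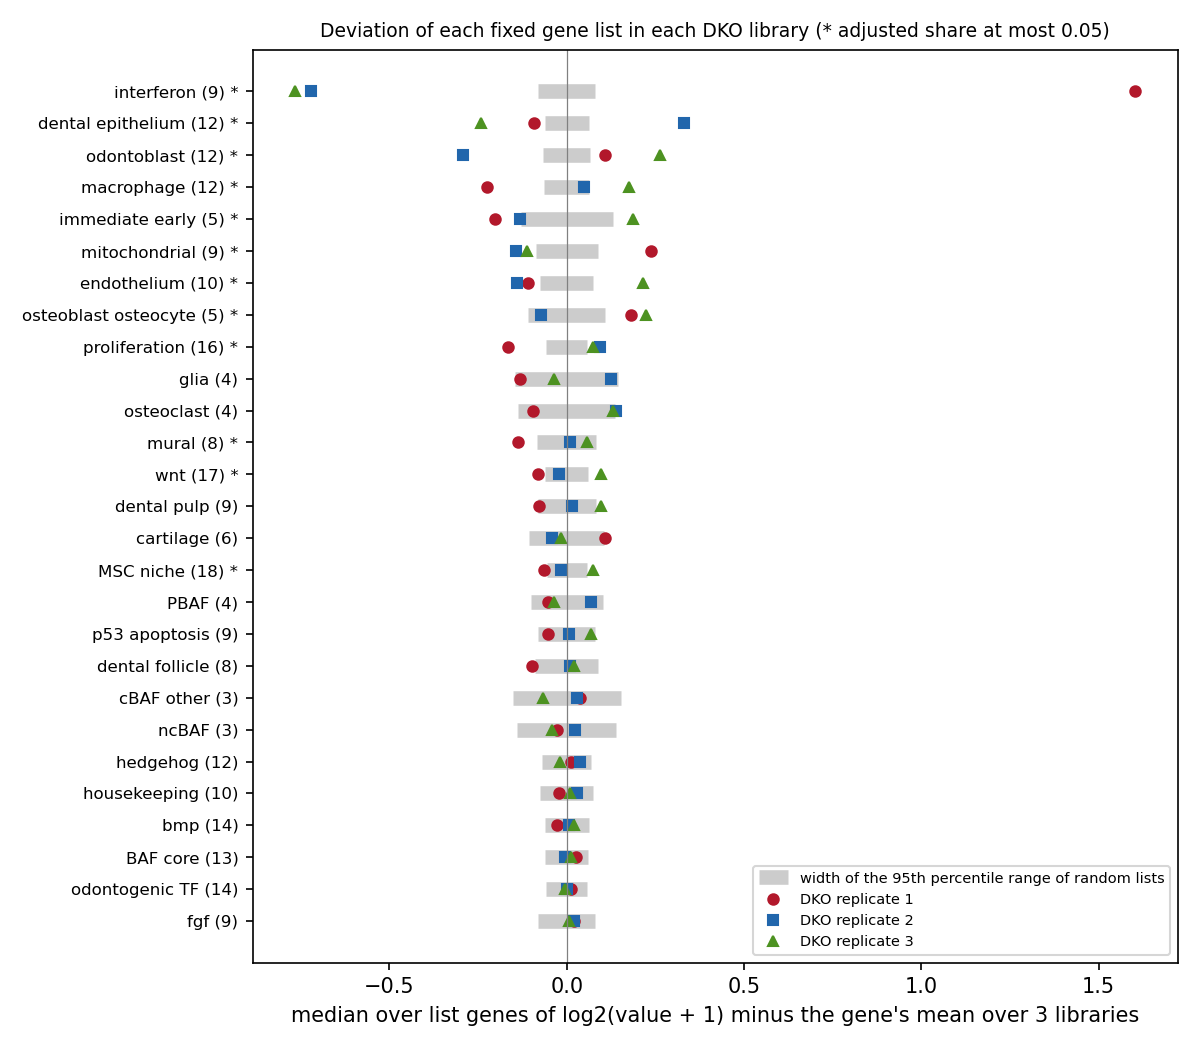
Median log2 deviation of each gene list from its members' means in the 3 DKO libraries, with a point for each library, the number of members in parentheses, a star at called lists and a grey bar as wide as the 95th percentile of the range of random lists. The interferon list spans 2.37, from 1.60 in replicate 1 to -0.77 in replicate 3, and the core BAF list spans 0.03.

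Within the hedgehog list, Shh, the ligand made by dental epithelium, was at 34.3, 33.1 and 0.885, 38.1-fold lower in replicate 3 than the mean of the others. Ptch1, a receptor and transcriptional target of the pathway, was at 665, 676 and 600, Gas1 at 404, 564 and 603, Gli3 at 247 ± 10.5 and Smo at 236 ± 6.24. Gli1, whose promoter drives the Cre, was at 45.7, 39.2 and 40.2 and was chosen after its values were seen. The list as a whole ranged over 0.05 (adjusted share 0.760).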

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

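The alternatives listed in the methods were planned, except removal of ribosomal RNA and mitochondrial genes and the changes of scaling and pseudocount for the count of variable genes and for gene levels, which were chosen after seeing the data. The differences between Arid1a, Arid1b and Arid2 kept their direction after division by exon length. Another pseudocount could not reverse them, and neither could leaving out a library, because every library had the same direction. The means of the 153 named genes moved by less than 1 SD when libraries were rescaled to equal totals. That rescaling could move means only slightly, because the totals were already close. Of 27 lists, 12 were called for spread. With genes of a mean of at least 100, 7 of 16 testable lists were called, 6 of them among the 12. Leaving out each library gave 3 to 9 called lists, the lowest without replicate 1, where odontoblast, dental epithelium and endothelial genes stayed called. The 5 lists called high became 14 with no filter on low values, 2 at a mean of at least 100 and 3 after division by exon length, and the 13 called low became 3, 28 and 22. Division by exon length also applied the filter of at least 10 to values per kilobase, so it changed length and filter together. The mean Spearman correlation of 0.980 was 0.988 with no filter, 0.948 at a mean of at least 100 and 0.975 to 0.985 with a library left out. Genes detected per library numbered 10353 on average at a value of at least 10, against 19381 above 0. The 49 genes with an SD of log2 above 1 became 93 with no filter, 15 with a pseudocount of 10 and 20 to 64 with a library left out, and 13 of the 20 left without replicate 1 were among the 49. With ribosomal RNA and mitochondrial genes removed, libraries rescaled to equal totals and 26 lists left to adjust over, 9 lists were called, and the niche list (adjusted share 0.121) and the mural list (0.121) were not. Only mitochondrial genes listed on the mitochondrial chromosome were removed, so their nuclear copies stayed in. Rescaling alone kept the calls of both. The cause was not tested for the other shifts. Scaling by trimmed means and tests on recovered reads were not run because whole reads were not recovered, and the planned summary of the authors' comparison had no columns to draw on in the table used here. Depth limits statements on genes with values near 1.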

Other observations

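All tests in this part were chosen after the results had been seen, and the genes named in it outside the fixed rule were chosen after their values were seen. Several genes with high means differed in replicate 1 without belonging to the interferon list. Ndnf, a secreted factor, was at 62.2, 171 and 190, and Postn, a matrix protein of the periodontal ligament, at 610, 1139 and 1337. Col3a1 was at 2100, 3325 and 3682. Outside the fixed list, other interferon-responsive genes were also highest in replicate 1, among them Ddx60 at 71.7, 11.6 and 10.8, Gbp6 at 137, 26.2 and 20.6 and Iigp1 at 154, 50.9 and 34.1. These examples were picked for that order. Gvin1, an interferon-inducible GTPase, was instead highest in replicate 3, at 9.49, 3.62 and 25.1.

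Processed pseudogenes gave some of the widest spreads. Rps3a3 was at 4.49, 2.82 and 139, and Rps3a2 at 31.3, 32.2 and 151, while the gene Rps3a1 was at 1039, 1042 and 687. The 3 together came to 1074, 1077 and 977. Rpl15-ps6 was at 33.5, 0.266 and 0.270, and Rpl15 with it came to 436, 443 and 445. Values of such copies are uncertain, because reads can be assigned to either.

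Interferon genes exceeded the mean of the other libraries in replicate 1 by a median log2 of 2.41 (bootstrap 95% interval over genes 1.96 to 2.55). The intervals in this part resample the genes of a list, which are regulated together, as if independent. They do not measure the spread between libraries. More macrophages in replicate 1 would raise their markers, but the 12 macrophage genes differed by -0.34 (-0.43 to -0.27), with 10 below 0. More macrophages were therefore argued against as the whole cause. The median of 10388 genes differed by -0.0112, but scaling to a common upper quartile keeps it near 0, so it does not test library scaling. Interferon and macrophage genes moved in opposite directions, which a common factor for all genes of a library would not produce. Removing the ribosomal RNA and mitochondrial genes, whose shares were highest in replicate 1, and rescaling to equal totals left the range of the interferon list at 2.40 (adjusted share 0.00043), against 2.37 as deposited. That step changed all remaining genes of a library by a common factor. It therefore could not remove the range, and a cause linked to those shares was not tested. An interferon response in the tissue of that library may account for the pattern, but with 1 group the design offers no biological contrast to test it.

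The 7 genes Dspp, Phex, Bglap, Bglap2, Col1a1, Col11a2 and Mmp20, picked because they were lowest in replicate 2, differed there by log2 values from -2.15 to -1.31, while Spp1, Amelx and Ambn were highest in that library. The odontoblast list had a median of -0.44 over 12 members, and the bone cell list with Ibsp a median of 0.0221 over 6 members that moved both ways. Neither value decides, because genes picked for a deficit exceed any wider list, so a lower share of odontoblasts and less bone tissue cannot be told apart. These tests were revised more than once after their results were seen, and earlier verdicts against less bone tissue and against an equal deficit of the odontoblast list were withdrawn. With 1 group, the design offers no biological contrast for this pattern.

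Shh was lower in replicate 3 by a log2 difference of -4.20 from the mean of the others. Less dental epithelium as the whole cause was argued against, because its 12 genes differed by -0.36 (-0.66 to 0.05). Fewer cells of an epithelial subset that makes Shh may contribute, and cannot be told apart from other causes because no markers of such a subset were fixed. Among genes with a mean of at least 10, 5 lay in replicate 3 below both other libraries by more than 3-fold, namely Shh, Otof (18.03, 18.19 and 0.466), Prom2 (20.48, 14.8 and 2.52), Kcnf1 (16.7, 15.1 and 3.12) and Col22a1 (14.7, 12.1 and 3.35), against 0 genes in replicate 1 and 8 in replicate 2.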
